A study of Mus musculus with 60 samples.

How the data were processed

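The data are 16S rDNA profiles of the small intestine of 60 mice, 10 in each of 6 groups named by the treatment in the labels. Per the labels, the contents were quickly removed from the small intestine and frozen, total DNA was extracted, and libraries were sequenced with an Illumina HiSeq protocol. The authors deposited 1 table of whole-number counts per OTU, with 1898 OTUs and 1 column per sample. The clustering tool, its identity threshold, the sequenced region, read filters and chimera removal are not given in the sources used here. A mouse genome build that the submitters' processing notes list has no role in counts of bacterial OTUs. The table pairs no OTU with a taxon, so OTUs are named by their number, which is not an identity. Lists of bacterial genera fixed before the data were examined, shares of phyla and all values per genus were therefore not computed, and every test planned on genera was run on OTUs. Of the table's columns, 60 matched a sample of this series by title, and 80 others matched none and were not used.

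The labels name separate samples but do not describe cages, litters or batches. The p-values therefore measure the spread between mice as labelled, and mice of one group that shared a cage are not independent. Total counts ran from 44340 to 67424 per mouse. PCR reads without molecular identifiers are not independent molecules, so counting intervals (95%, exact Poisson) and the floor of 3 counts cover counting error only. Folds against a group with 0 counts are lower bounds against 3 counts over that group's total, and with 1 to 3 counts the ratio of the mean share to the pooled share is given with its counting interval.

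Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F test, robust) on all 60 samples in one fit without covariates. The 559 OTUs counted in at least 10 samples were tested; they hold 98.8% of all counts, and 209 OTUs of the table had no count here. The 9 pairs of groups and the interaction of AOS with HFD-STZ were tested, each with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. TMM factors ran from 0.213 to 4.44, and dropping them shifted the log2 fold changes of single OTUs by a median of -0.46 to 0.52, depending on the comparison, so the split into higher and lower is relative to the scaling. Alternatives were total counts without TMM, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log-ratios with a pseudocount of 0.5, no filter, edgeR's filterByExpr, a fit that is not robust, only the 2 groups compared, and the replicate number as a block. A two-sided permutation test per OTU on log2 of the share in percent plus 0.001 and Fisher's exact test on carriage were added after the data were examined.

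The named OTUs follow a rule fixed before the data were examined. For each pair they are the 2 with the largest rise and the 2 with the largest fall in log2 fold change among OTUs past the threshold, with a mean share of at least 0.1% in 1 of the groups and carried by at least 5 mice of the higher group. OTU6, OTU1 and the OTUs named only with the 3 against 3 split of the groups were chosen after their values were seen.

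Community differences were tested with PERMANOVA (vegan 2.7.1, 99999 permutations) on Bray-Curtis dissimilarity of shares, with the spread around group centres beside it. Single measures were compared by two-sided permutation tests with 1e+05 resamples. Observed OTUs and the Shannon index are means of 20 draws of 44340 counts per mouse. Jaccard dissimilarity and Aitchison distance were chosen beside it before the data were examined. Random splits of the samples numbered 100 per comparison, the random dealings of the HFD-STZ mice 40 and the halvings 20. Simulations of unchanged groups numbered 40 and set a weak bar, since they draw around the HFD-STZ means and so leave out these mice's own chance deviation, which the dealings include.

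The edgeR step was tested on negative binomial counts simulated from the pooled share of each OTU, the real library sizes and edgeR's own dispersions, a model that favours edgeR. In HFD-STZ against control, 200 of 549 OTUs were changed. edgeR recovered 42 of 100 OTUs changed 8-fold and 85 of 100 changed 64-fold, and it called 14 of 349 unchanged OTUs. On the same counts DESeq2 recovered 31 and 75 and called 8 unchanged OTUs, limma on centred log-ratios 16 and 50 with 4, and the permutation test 4 and 9 with 4. For edgeR, and for each of the others, unchanged OTUs were a larger part of the calls than the threshold of 0.05. That threshold was thus not held here, even for edgeR under a model that favours it, and edgeR's calls below can hold more false ones than it states.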

Results

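The bacterial 16S rRNA gene was sequenced from the small intestine of 60 ICR mice, an outbred strain, all aged 10 weeks. The mice formed 6 groups of 10. Untreated control mice and mice given AOS at 10 mg/kg (the labels do not spell AOS out) stood beside mice on a high fat diet with STZ. STZ is streptozotocin, a compound toxic to the insulin-producing beta cells, and these mice are called HFD-STZ. Further HFD-STZ mice were given AOS at 10 mg/kg (HFD-STZ+AOS), faecal microbiota transplantation (FMT) named for AOS (HFD-STZ+AOS-FMT), or FMT named for control (HFD-STZ+control-FMT). FMT moves gut microbes from a donor into a recipient. Each mouse had 44340 to 67424 counts, and 1689 operational taxonomic units (OTUs, clusters of near-identical 16S sequences) had at least 1 count. In a single mouse, 0 counts of an OTU allowed a share of up to 0.00445% to 0.00677% of the counts, depending on its depth. The design text asks how FMT acts on a small intestine damaged by the diet and STZ. Over all 60 mice, group membership accounted for 25.6% of the variation in Bray-Curtis dissimilarity (PERMANOVA, p = 1e-05, the smallest that the permutations can give).

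**Figure D1:**
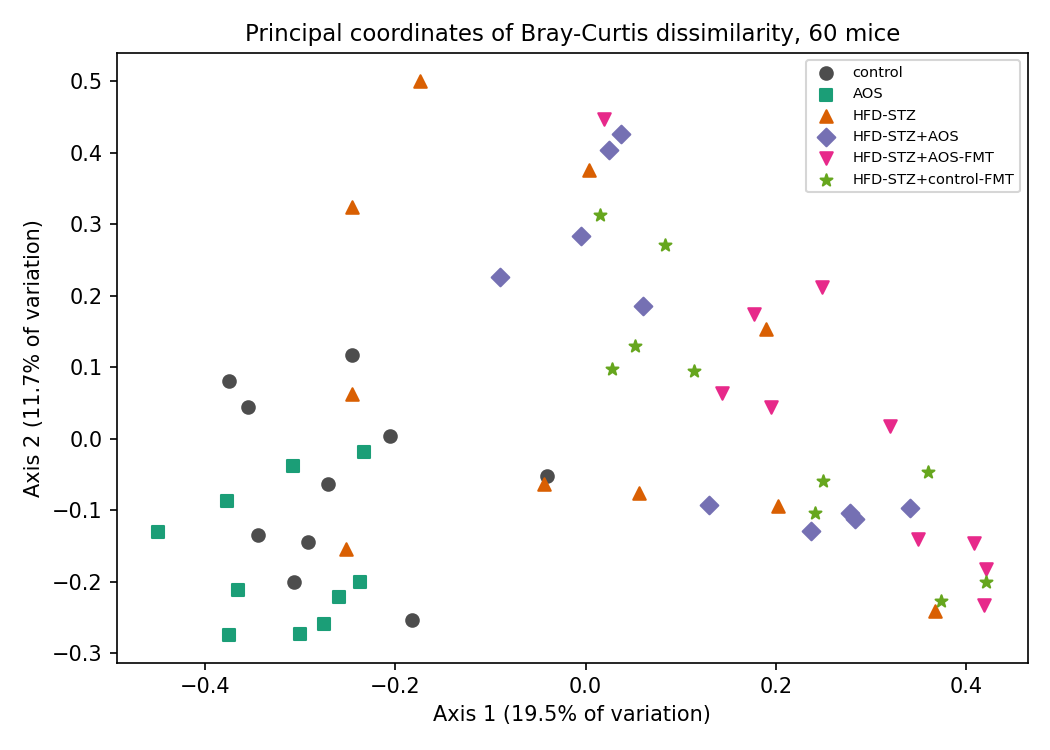
Principal coordinates of Bray-Curtis dissimilarity between the 60 mice, with 1 point per mouse and 1 symbol per group; axis 1 holds 19.5% and axis 2 holds 11.7% of the variation. All 10 control and all 10 AOS mice lie below 0 on axis 1, the 10 HFD-STZ mice range from -0.25 to 0.37, and all 20 FMT recipients lie above 0.

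HFD-STZ mice were compared with control mice to describe the effect of the diet and STZ. OTU38 made up 1.45% ± 4.13 of the counts in HFD-STZ mice (SD, n = 10) and was detected in 5 of them and in no control mouse, so that it was at least 2916-fold higher against a floor of 3 counts over the control group. OTU87 averaged 0.204% ± 0.564 in HFD-STZ mice, was carried by 6 of 10 and was not detected in controls, at least 408-fold higher. OTU16 fell from 1.33% ± 2.20 in controls, where 7 of 10 mice carried it, to 2 counts in 1 HFD-STZ mouse, a 4125-fold ratio (95% counting interval 1142 to 34058). OTU94 fell from 0.324% ± 0.407 in controls, where 9 of 10 carried it, to 1 count in 1 HFD-STZ mouse, a 2005-fold ratio (95% counting interval 359.9 to 79204). By edgeR's quasi-likelihood test, 157 of 559 OTUs passed an adjusted p of 0.05, 70 of them higher and 87 lower in HFD-STZ mice, and scaling by total counts instead gave 53 higher and 108 lower. The 70 higher OTUs summed to 21.4% ± 21.4 of the counts in HFD-STZ mice and to 0.467% ± 0.507 in controls. The 87 lower OTUs summed to 0.0408% ± 0.0387 in HFD-STZ mice and to 17.1% ± 15.1 in controls. Such sums, here and below, are of OTUs chosen by their direction in the same mice, so their contrast is no separate evidence. The whole community differed as well, with group accounting for 11.6% of the variation (PERMANOVA, adjusted p = 0.0147). The spread around the group centre was 0.539 in HFD-STZ and 0.459 in control mice (p = 0.0155, adjusted p = 0.140). DESeq2 called 60 OTUs (31 higher), limma on centred log-ratios 48 (17 higher) and a permutation test per OTU 2, both lower in HFD-STZ mice, 1 of them OTU94 (adjusted p = 0.0475). A single mouse held 90.3% of the group's OTU38 and 88.2% of its OTU87, and in 105 of the 157 calls 1 mouse held over 50% of the summed share of the higher group.

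AOS was compared with control in mice without the diet and STZ. OTU44 made up 1.57% ± 2.62 of the counts in AOS mice, where 8 of 10 carried it, and 0.000986% ± 0.00312 in controls, where 1 did (log2 fold change 9.27, SE 2.06, edgeR adjusted p = 0.00358). OTU118 averaged 0.489% ± 0.728 in AOS mice, carried by 8 of 10, and 0.0124% ± 0.0393 in controls, carried by 1 (log2 fold change 7.25, SE 1.78, edgeR adjusted p = 0.00787). In HFD-STZ+AOS mice, OTU44 and OTU118 were carried by 2 and 1 of 10. No OTU with a share of at least 0.1% passed the test in the lower direction. edgeR called 6 OTUs, 5 higher and 1 lower (4 higher and 3 lower with total counts), DESeq2 4 (3 higher) and limma on centred log-ratios 33 (30 higher). Group accounted for 8.97% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 0.0715), 7.42% in Jaccard dissimilarity on presence (adjusted p = 0.0705) and 8.62% in Aitchison distance (adjusted p = 0.0486). The permutation test per OTU called 0 OTUs, with 41 at an unadjusted p under 0.05, and the 2 named OTUs had an adjusted p of 0.638 there.

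HFD-STZ+AOS mice were compared with HFD-STZ mice to describe AOS given on top of the diet and STZ. OTU8 made up 4.12% ± 9.88 of the counts in HFD-STZ+AOS mice (5 of 10 carriers) and 0.00222% ± 0.00547 in HFD-STZ mice (3 of 10), with a log2 fold change of 12.06 (SE 2.44, edgeR adjusted p = 0.000211). OTU48 averaged 0.395% ± 1.23 against 0.00406% ± 0.0101 (log2 fold change 8.99, SE 2.34). OTU9 fell from 3.09% ± 5.95 in HFD-STZ mice, where 9 of 10 carried it, to 0.00637% ± 0.0116, where 4 did (log2 fold change -9.99, SE 2.08, edgeR adjusted p = 0.000233). OTU40 fell from 2.39% ± 5.95 with 8 carriers to 0.00219% ± 0.00694 with 1 carrier (log2 fold change -11.84, SE 2.20). edgeR called 159 OTUs, 49 higher and 110 lower, and with total counts 75 higher and 89 lower. DESeq2 called 59 (14 higher) and limma on centred log-ratios 15 (3 higher). Group accounted for 5.98% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 0.299). It accounted for 10.1% in Jaccard dissimilarity on presence (adjusted p = 0.00163) and for 11.6% in Aitchison distance (adjusted p = 0.00249). The permutation test per OTU called 0 OTUs, with 53 at an unadjusted p under 0.05, and 1 HFD-STZ+AOS mouse held 98.9% of that group's OTU48 and 74.3% of its OTU8, while single HFD-STZ mice held 79.6% of the OTU40 and 62.4% of the OTU9 in HFD-STZ mice.

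AOS-FMT recipients were compared with HFD-STZ mice to describe what followed transplantation named for AOS. OTU43 was carried by 10 of 10 HFD-STZ mice at 0.454% ± 0.785 of the counts and was not detected in any of the 10 recipients, at least 905-fold lower, a difference that also passed the permutation test (adjusted p = 0.00140). OTU11, at 1.82% ± 4.97 in HFD-STZ mice with 8 carriers, was likewise not detected in the recipients, at least 3626-fold lower (permutation test, adjusted p = 0.0391). OTU18 rose from 3 counts in 1 HFD-STZ mouse to 1.29% ± 2.64 with 7 carriers, a 2669-fold ratio (95% counting interval 913 to 12942). OTU8 rose to 5.11% ± 6.89 with 8 carriers (log2 fold change 11.37, SE 2.38, edgeR adjusted p = 0.000306). The 110 OTUs called lower by edgeR summed to 36.5% ± 22.9 of the counts in HFD-STZ mice and to 0.457% ± 0.686 in the recipients, and the 73 called higher summed to 0.0889% ± 0.116 and 10.9% ± 8.50. Of the 183 calls, 6 higher and 5 lower OTUs were also called by the permutation test. DESeq2 called 75 OTUs (22 higher) and limma on centred log-ratios 65 (32 higher). Group accounted for 11.7% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 0.0245). The spread around the group centre was 0.447 in recipients and 0.539 in HFD-STZ mice (permutation test of the spread, p = 0.0664, adjusted p = 0.199). OTU18 and OTU8 did not pass the permutation test (adjusted p = 0.0838 and 0.0629), and single mice held 87.6% of the OTU11 and 57.2% of the OTU43 in HFD-STZ mice and 56.4% of the OTU18 in recipients.

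Control-FMT recipients were compared with HFD-STZ mice as the transplantation without AOS in its name. OTU8 was carried by all 10 recipients at 7.48% ± 12.3 and by 3 of 10 HFD-STZ mice at 0.00222% ± 0.00547 (log2 fold change 12.77, SE 2.50), a rise that also passed the permutation test (adjusted p = 0.00419). OTU18 rose from 3 counts in 1 mouse to 1.03% ± 2.58 with 9 carriers, a 2121-fold ratio (95% counting interval 725.7 to 10285; permutation test, adjusted p = 0.00950). OTU40 fell from 2.39% ± 5.95 with 8 carriers to 1 count in 1 mouse, a 14665-fold ratio (95% counting interval 2632 to 579244; permutation test, adjusted p = 0.0246). OTU11 was not detected in the recipients, at least 3712-fold lower than in HFD-STZ mice (permutation test, adjusted p = 0.0217). edgeR called 225 OTUs, 125 higher and 100 lower, and the permutation test 38, of which 26 were higher and 12 lower. DESeq2 called 91 (30 higher) and limma on centred log-ratios 89 (43 higher). The 125 higher OTUs summed to 17.6% ± 16.7 of the counts in recipients and to 0.183% ± 0.169 in HFD-STZ mice. Group accounted for 11.9% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 0.0147). Single mice held 80.7% of the OTU18 and 51.8% of the OTU8 in recipients, and 79.6% of the OTU40 and 87.6% of the OTU11 in HFD-STZ mice.

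**Figure D2:**
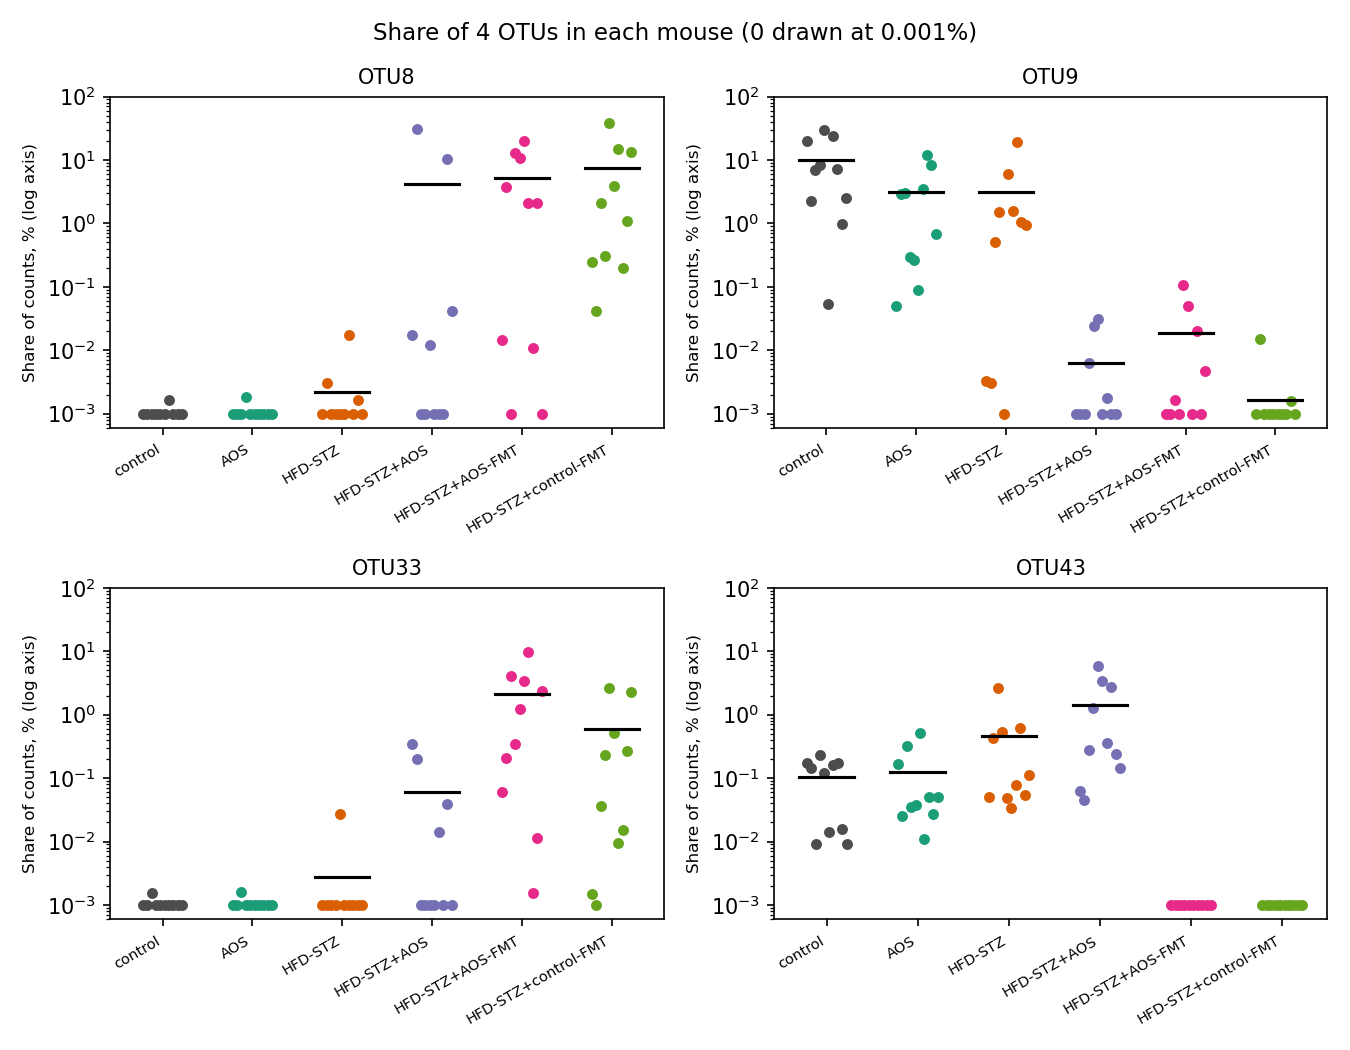
Share of counts of OTU8, OTU9, OTU33 and OTU43 in each of the 60 mice, in percent on a log axis, with 0 drawn at 0.001%; bars are group means, and no bar is drawn where the mean is 0. OTU43 was detected in all 10 mice of each of the 4 groups without FMT and in 0 of the 20 FMT recipients, and OTU9 averaged 10.1% in controls and 0.00166% in control-FMT recipients.

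The 2 kinds of FMT were compared directly to describe what the treatment of the named donor added. OTU464 made up 0.343% ± 0.639 of the counts in AOS-FMT recipients and 11.3% ± 16.7 in control-FMT recipients, and all 10 mice of both groups carried it (log2 fold change -6.20, SE 1.84, edgeR adjusted p = 0.0231, permutation test adjusted p = 0.858). OTU84 averaged 0.00164% ± 0.00520 with 1 carrier against 0.237% ± 0.734 with 5 carriers (log2 fold change -5.93, SE 1.68, edgeR adjusted p = 0.0161), and 1 control-FMT mouse held 98.2% of it. No OTU with a share of at least 0.1% was called higher in AOS-FMT recipients. edgeR called 40 OTUs, 7 higher and 33 lower, DESeq2 7 (4 higher), limma on centred log-ratios 1, and the permutation test 0, with 27 at an unadjusted p under 0.05. Group accounted for 7.98% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 0.138). Each recipient's dissimilarity to control mice minus its dissimilarity to AOS mice was -0.0233 ± 0.0165 after AOS-FMT and -0.0223 ± 0.0157 after control-FMT (difference -0.00105, two-sided permutation test, p = 0.884), and it was -0.0283 ± 0.0525 in HFD-STZ and -0.0273 ± 0.0289 in HFD-STZ+AOS mice, so that a lean towards control was not particular to recipients. The labels do not say whether the control and AOS mice measured here were the donors.

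Each treated group was also set against control mice to describe what remained different. OTU9, at 10.1% ± 10.4 of the counts and carried by all 10 controls, stood at 0.00637% ± 0.0116 in HFD-STZ+AOS mice and at 0.00166% ± 0.00473 in control-FMT recipients (log2 fold changes -12.12 and -13.10, permutation test adjusted p = 0.00335 and 0.00112). OTU16 was not detected in AOS-FMT recipients, at least 2656-fold lower than in controls (permutation test, adjusted p = 0.0262), and neither was OTU11, at least 797-fold lower (adjusted p = 0.0580). OTU33 was at 1 count in 1 control mouse and at 2.13% ± 3.04 in AOS-FMT recipients, all 10 of which carried it, a 12805-fold ratio (95% counting interval 2298 to 505761; permutation test, adjusted p = 0.00186). OTU21 rose to 2.07% ± 4.68 in HFD-STZ+AOS mice from 0.00125% ± 0.00344 in controls (log2 fold change 12.60, SE 2.53, permutation test adjusted p = 0.0377). The naming rule tied these OTUs to single pairs, but the changes were not particular to those groups. OTU33 averaged 0.600% with 9 carriers after control-FMT. OTU21 averaged 2.24% with 9 carriers after AOS-FMT and 0.934% with 10 after control-FMT. OTU16 had 9 counts in HFD-STZ+AOS mice and 7 after control-FMT, and OTU9 averaged 0.0184% after AOS-FMT. OTU8 was at 1 count in 1 control mouse and higher in all 3 treated groups, with a permutation test's adjusted p of 0.129 after AOS, 0.0105 after AOS-FMT and 0.00112 after control-FMT. OTU255 was not detected in controls and averaged 0.264% ± 0.440 in control-FMT recipients with 6 carriers (0.185% with 9 carriers after AOS-FMT), and OTU76, at 0.519% ± 1.38 in controls with 5 carriers, was not detected in HFD-STZ+AOS mice. Neither passed the permutation test (adjusted p = 0.0594 and 0.129), and single mice held 84.9% of the OTU76 and 83.3% of the OTU11 in controls, 73.4% of the OTU21 and 74.3% of the OTU8 in HFD-STZ+AOS mice, and 51.8% of the OTU8 in control-FMT recipients. edgeR called 284 OTUs in HFD-STZ+AOS mice (91 higher), 276 after AOS-FMT (91 higher) and 277 after control-FMT (126 higher). The permutation test called 55, 78 and 78, DESeq2 140, 126 and 138, and limma on centred log-ratios 121 (67 higher), 139 (74 higher) and 150 (73 higher). Group accounted for 18.5%, 27.5% and 23.6% of the variation in Bray-Curtis dissimilarity (PERMANOVA, adjusted p = 3e-05 each, from the smallest p that the permutations can give). In AOS-FMT recipients the 91 higher OTUs summed to 64.7% ± 17.2 of the counts, against 1.68% ± 2.09 in controls, and the 185 lower OTUs to 0.713% ± 1.30, against 62.9% ± 16.99.

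The distance to control asked whether a treated group lay nearer to control mice than HFD-STZ mice did. The mean Bray-Curtis dissimilarity to the 10 controls was 0.790 ± 0.0766 in HFD-STZ mice, 0.834 ± 0.0815 in HFD-STZ+AOS mice, 0.862 ± 0.0574 in AOS-FMT recipients and 0.838 ± 0.0502 in control-FMT recipients (SD, n = 10 each). No treated group had a lower mean than HFD-STZ mice. The differences did not pass the two-sided permutation test after adjustment for 3 comparisons (p = 0.222, 0.0285 and 0.113; adjusted p = 0.222, 0.0854 and 0.169). With Jaccard dissimilarity on presence all 3 treated groups were farther from control than HFD-STZ mice (adjusted p = 0.000780, 0.000120 and 0.00144), and with Aitchison distance both FMT groups were (adjusted p = 0.0321 and 0.0309).

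**Figure D3:**
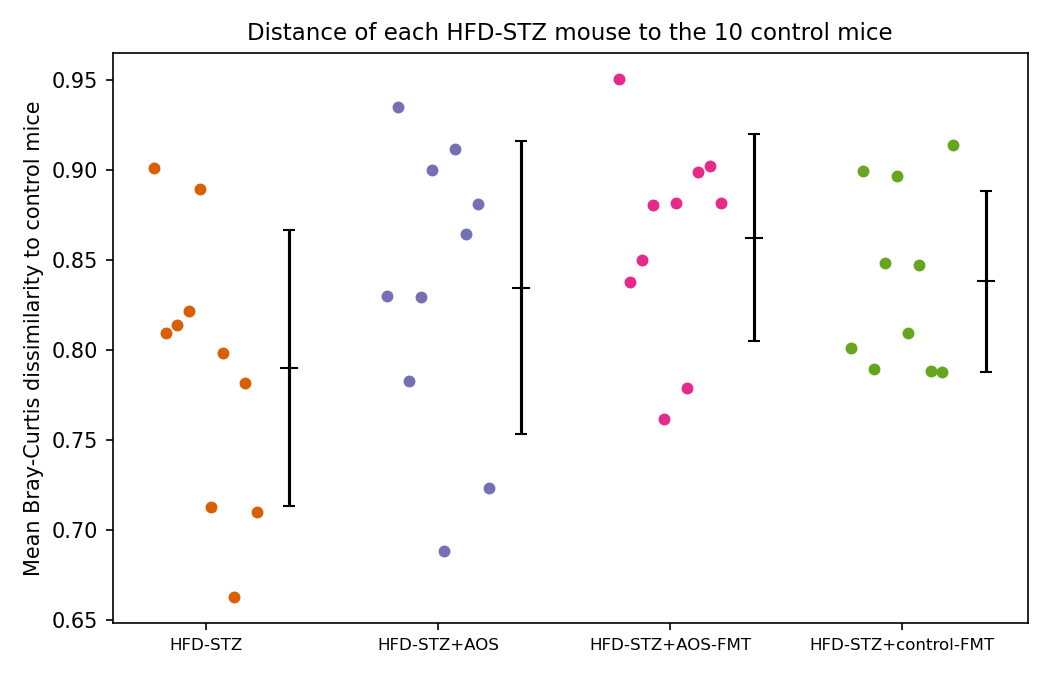
Mean Bray-Curtis dissimilarity (no unit, 0 for identical and 1 for disjoint communities; the axis starts above 0) of each mouse to the 10 control mice in the 4 HFD-STZ groups, with 1 point per mouse and a bar for the mean ± SD. The means are 0.790, 0.834, 0.862 and 0.838 from left to right.

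Of the 157 OTUs called between HFD-STZ and control mice, 31 were called the opposite way in HFD-STZ+AOS against HFD-STZ, 41 in AOS-FMT recipients and 47 in control-FMT recipients. Those called the same way as in HFD-STZ numbered 4, 6 and 5. These comparisons share the HFD-STZ mice, which alone gives opposite signs. Simulated unchanged groups gave a mean of 0.15, 0.1 and 0.125 opposite calls and 0 in the same direction, around means fixed at those of the HFD-STZ mice. When the 40 mice of the 4 HFD-STZ groups were dealt out at random among the 4 group names 40 times, the mean number of opposite calls was 23.95, 19.6 and 21.4, and 13, 3 and 4 of the 40 dealings reached the real number. A dealing could put treated mice under the HFD-STZ name. How many OTUs that name then gave against control was not recorded, so these counts may rest on lists longer or shorter than 157. When the HFD-STZ mice were split 5 and 5, with 1 set in each comparison, the mean number called the opposite way was 8.65, 7.45 and 11.85 and the mean number called the same way was 13.4, 13.95 and 12.8. The set of 5 compared with control gave a mean of 117.75 called OTUs.

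The same OTUs recurred among the calls of the 3 treated groups against HFD-STZ. The FMT groups shared 60 OTUs called higher and 84 called lower, AOS and AOS-FMT shared 32 and 77, and AOS and control-FMT shared 36 and 71. Independent lists of these sizes would share 16.3 and 19.7, 6.40 and 21.6, and 10.96 and 19.7. These lists are not independent, since all are against the same HFD-STZ mice, so an excess over these numbers is partly built in. Unchanged groups simulated against the same HFD-STZ mice shared 0 OTUs, a low bar given their few calls among the 157 OTUs. Random dealing of the 40 mice gave at most 20 and 21, 30 and 23, and 47 and 26, the 47 being above the real 36. With separate sets of 5 HFD-STZ mice in the 2 comparisons the means were 14.45 and 38.7, 5.95 and 32.8, and 5.75 and 38.3.

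The effect of AOS in HFD-STZ mice was set against its effect in untreated mice by an interaction test in edgeR, which called 145 OTUs, 47 with a higher and 98 with a lower log2 fold change in HFD-STZ mice. Scaling by total counts gave 63 and 82. DESeq2 called 40 OTUs (13 higher) and limma on centred log-ratios 18 (4 higher). The permutation test per OTU was not run on the interaction.

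The number of observed OTUs at equal depth was 283 ± 82.8 in control, 309 ± 80.9 in AOS, 208 ± 31.9 in HFD-STZ, 199.5 ± 69.1 in HFD-STZ+AOS, 232 ± 88.7 in AOS-FMT and 267 ± 81.9 in control-FMT mice (SD, n = 10 each). No pair passed the two-sided permutation test after adjustment for 9 pairs, the lowest p being 0.0157 for HFD-STZ against control (adjusted p = 0.119). The Shannon index was 2.75 ± 0.59, 3.09 ± 0.73, 2.37 ± 0.63, 2.33 ± 0.48, 2.12 ± 0.44 and 2.45 ± 0.47 in the same order. Its lowest p was 0.0166, for AOS-FMT against control (difference -0.63, adjusted p = 0.149).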

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

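The tests of the distance pattern and of the core, and the splits for HFD-STZ against control, were chosen or partly run after the result was seen, and the splits for the other comparisons before.

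Of 36 combinations of a measure and a group, 3 held a mouse far from the rest by Dixon's test, where chance gives about 1 in 20. Control replicate 5 had 95.4 observed OTUs at equal depth, and the next lowest control had 233. HFD-STZ+AOS-FMT replicate 7 had 450.0 observed OTUs, and the next highest of its group had 306. In AOS replicate 6 the most abundant OTU took 55.4% of the counts, against 29.6% in the next mouse.

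edgeR's interaction test called 145 OTUs for a difference in the AOS effect between HFD-STZ and untreated mice. Only the real one of 100 splits of the AOS labels within each background called as many OTUs, and the highest of the others called 83. This argues against a random grouping as the source of the count. DESeq2, however, called 40, limma on centred log-ratios 18 and the fit blocked by replicate number 1. The splits cannot separate AOS from a cohort or batch of the HFD-STZ+AOS mice, which the labels do not give. In the pairs, 1 of 100 splits, the real one, called as many OTUs for HFD-STZ against control (157, highest other 115), HFD-STZ+AOS against HFD-STZ (159, 128), control-FMT against HFD-STZ (225, 128), AOS-FMT against control-FMT (40, 29), and HFD-STZ+AOS, AOS-FMT and control-FMT against control (284, 276 and 277, with 184, 162 and 131). For AOS-FMT against HFD-STZ 2 of 100 splits reached the real 183, the highest other being 183 as well, so a random grouping is argued against less clearly there. For AOS against control 30 of 100 splits called at least the real 6 OTUs, the highest 31, so a random grouping gives such a count. Random splits called a median of 4 to 53 OTUs, so edgeR calls OTUs in these sparse counts where the split does not follow the treatment. The splits were not balanced for treatment, so part of a real difference can enter them, and these medians are not a rate of false calls.

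The mean Bray-Curtis dissimilarity to control mice was 0.0723 higher in AOS-FMT recipients than in HFD-STZ mice, without passing the test (adjusted p = 0.0854). The tables argue against 1 dominant OTU per library as the whole cause, since the difference was 0.0617 without each library's most abundant OTU (adjusted p = 0.0434), and against a few HFD-STZ mice near control, since the medians differed by 0.0772 (95% resampling interval 0.00729 to 0.169). Unequal library depth is argued against as well, since the difference was still 0.0722 with every library rarefied to the smallest (two-sided permutation test, adjusted p = 0.0861). An animal cohort or sequencing batch cannot be told apart from the treatments, because the labels give neither. At equal depth, 6 OTUs were carried by at least 5 mice of each of control, AOS and HFD-STZ and at most 1 mouse of each other group, or the reverse. No other division of the groups into 3 and 3 had any. Unequal divisions had more by the same rule, with 10 OTUs carried in AOS mice alone, and 8 in control and AOS mice with 2 the reverse. A treatment effect of AOS and FMT stays open too, as does chance.

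AOS mice shared more OTUs than control mice, with 78 against 47 carried by at least 9 of 10 mice in counts rarefied to equal depth (two-sided permutation test, p = 0.0323). Control replicate 5, the library with few OTUs, fits as the source of most of this gap. With 9 mice of each group and at least 8 carriers, the difference was 12.6 OTUs without that mouse and 27.6 to 37.6 OTUs when any other control was left out. At 9 of 9 carriers it was 6.3 against 28.3 to 30.3. With all 10 AOS mice kept, the difference without control replicate 5 was 5 OTUs (78 against 73, two-sided permutation test, p = 0.701). That count took at least 9 of 10 AOS carriers and at least 8 of 9 control carriers. An effect of AOS or a shared cage may account for what remains, which no test here called.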

How the results depend on the processing

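The permutation test per OTU, the carriage test, the fits without control replicate 5, the shared OTUs of AOS and control mice with single mice left out and the distances on rarefied counts or without the most abundant OTU were chosen after seeing the data. Planned values per genus and shares of taxon lists were not run, since no taxon is paired with an OTU. Values are in the order HFD-STZ, AOS (both against control), HFD-STZ+AOS, AOS-FMT, control-FMT (against HFD-STZ), AOS-FMT against control-FMT, then HFD-STZ+AOS, AOS-FMT and control-FMT against control.

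Total numbers of called OTUs stayed within 1.5 times with total counts, without robust fitting, with only the 2 groups compared and without control replicate 5. The split by direction could move more. For control-FMT against HFD-STZ, 125 higher and 100 lower became 98 and 97 with total counts. With only the 2 groups compared they became 66 and 112. DESeq2 gave 60, 4, 59, 75, 91, 7, 140, 126 and 138, and 40 for the interaction. limma on centred log-ratios gave 48, 33, 15, 65, 89, 1, 121, 139 and 150, and 18 for the interaction. filterByExpr, which tests only 169 OTUs, gave 46, 0, 54, 59, 71, 5, 89, 94 and 92, and 47 for the interaction; its 0 for AOS came with 16 at an unadjusted p under 0.05. Without a filter, over 1689 OTUs, the counts were 204, 45, 253, 224, 392, 93, 453, 436 and 467, and 102 for the interaction. The permutation test gave 2, 0, 0, 11, 38, 0, 55, 78 and 78, with 41, 53 and 27 OTUs at an unadjusted p under 0.05 where it gave 0. Fisher's exact test on carriage gave 2, 0, 0, 7, 2, 0, 19, 20 and 18, with 9, 26 and 8 at an unadjusted p under 0.05 where it gave 0. On the simulated counts, from a model that favours edgeR, edgeR recovered 85 of 100 OTUs changed 64-fold, DESeq2 75, limma 50 and the permutation test 9. The tools thus differ in recovery under that model, and few calls by the permutation test are weak evidence of no change. Unchanged OTUs also made up a larger part of each tool's calls there, edgeR's included, than the adjustment threshold. The cause of the gap in the real counts was not tested further.

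The replicate numbers of the titles as a block gave 9, 25, 4, 14, 19, 0, 115, 119 and 138 calls, and 1 for the interaction; the 0 came with 45 OTUs at an unadjusted p under 0.05. Mice with the same number showed little common deviation on average (mean correlations between -0.109 and 0.134, and in no pair of groups all above 0.1). Only 3 to 8 numbers were shared per pair of groups, and single correlations reached 0.414, so pairing by number cannot be excluded. In PERMANOVA, swaps within shared numbers kept the side of 0.05 in the 5 pairs that share at least 5 numbers. Their p was not adjusted, unlike that of the main test. For AOS-FMT against HFD-STZ it was 0.03125, the smallest that 32 swaps can give, so that call rests on an unadjusted p.

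Some PERMANOVA calls passed only under another distance: 10.1% of the variation with Jaccard and 11.6% with Aitchison for HFD-STZ+AOS against HFD-STZ, and 8.62% with Aitchison for AOS against control (adjusted p = 0.0486), which is below the 8.97% with Bray-Curtis. Other PERMANOVA calls kept their side of the threshold. The distance to control passed with Jaccard (differences 0.0509, 0.0619 and 0.0433 for AOS, AOS-FMT and control-FMT), with Aitchison for both FMT groups (7.69 and 9.01) and without the most abundant OTU for AOS-FMT (0.0617), each farther from control; over all alternatives the adjusted p ran from 0.000120 to 0.306. The likeness to AOS against control mice changed sign with Aitchison (0.0459, p = 0.939) and without the most abundant OTU (0.0117, p = 0.211), and passed nowhere. Shannon index and observed OTUs kept their direction and side under both alternatives run. The numbers of OTUs called the opposite way after treatment fell to 6, 7 and 5 with DESeq2. It called only 60 OTUs between HFD-STZ and control mice, against 157 by edgeR, so part of this fall is a shorter list. With 5 HFD-STZ mice in each comparison the numbers fell to means of 8.65, 7.45 and 11.85, among a mean of 117.75 called OTUs. There, fewer mice enter each comparison and no HFD-STZ mouse enters both, so the drop cannot be put down to either alone.

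Among the named OTUs, which were 32 results, no direction changed under any alternative run, and filterByExpr covered 26 of them. The call was lost for 18 with the permutation test, 12 with the replicate block, 9 with limma, 2 with DESeq2 and 1 each with total counts and without a filter. Depth limits carriage, since an OTU below about 0.00445% to 0.00677% of a mouse's counts can be missed.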

Other observations

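The OTUs of these paragraphs were singled out after their values were seen. OTU6, which made up 0.0384% ± 0.0515 of the counts in control mice and 0.215% ± 0.650 in AOS mice (SD, n = 10), averaged 10.4% ± 18.99 in HFD-STZ, 9.46% ± 17.99 in HFD-STZ+AOS, 18.8% ± 22.03 in AOS-FMT and 15.4% ± 17.8 in control-FMT mice. Against control its log2 fold change was 8.61 (SE 2.18) in HFD-STZ mice by edgeR (adjusted p = 0.00122; permutation test, adjusted p = 0.127) and 8.81 (SE 2.20) in HFD-STZ+AOS mice (adjusted p = 0.000589; permutation test, adjusted p = 0.129). The permutation test called it after AOS-FMT (adjusted p = 0.0128) and control-FMT (adjusted p = 0.01002). In 5 of 10 HFD-STZ and 4 of 10 HFD-STZ+AOS mice it lay within the control range of 0 to 0.136%, and 1 mouse of each of these groups held 54.2% and 58.8% of its OTU6. OTU1 stood at 15.4% ± 20.1 in control and 12.98% ± 22.5 in HFD-STZ mice, and at 0.269% ± 0.611 and 0.279% ± 0.821 after AOS-FMT and control-FMT. Both falls from control passed the permutation test (adjusted p = 0.00910 and 0.00483). HFD-STZ+AOS mice averaged 7.91% ± 16.1, a mean that rests on 2 mice at 39.98% and 36.8%, with the others at 1.40% or less. Of the OTU1 in HFD-STZ mice, 1 mouse at 62.7% held 48.4%.

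OTU43 was carried by all 10 mice of each group without FMT, at 0.105% ± 0.0844 in control, 0.124% ± 0.167 in AOS, 0.454% ± 0.785 in HFD-STZ and 1.43% ± 1.94 in HFD-STZ+AOS mice, and had 0 counts in all 20 FMT recipients. It was the only OTU carried by at least 5 mice of each group without FMT and by at most 1 mouse of each FMT group at equal depth. Of the 6 OTUs that divide control, AOS and HFD-STZ from the other 3 groups, OTU132 was the 1 carried by the other side, by 5, 10 and 8 of 10 mice in HFD-STZ+AOS, AOS-FMT and control-FMT. The 5 carried by the first side were OTU55, OTU400, OTU563, OTU634 and OTU1141, of which OTU55 was the most abundant in control (0.718%) and HFD-STZ mice (0.864%) and OTU1141 in AOS mice (0.282%). Of the 47 OTUs carried by at least 9 of 10 control mice, 40 were carried that widely in AOS, 19 in HFD-STZ, 16 in HFD-STZ+AOS, 12 in AOS-FMT and 14 in control-FMT mice. These groups carried 78, 32, 32, 44 and 47 OTUs that widely, which limits how many can be shared. The 47 also depend on control replicate 5, without which 73 OTUs were carried by at least 8 of 9 controls.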
